A study of Drosophila melanogaster with 8 samples.

How the data were processed

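Open chromatin was measured by FAIRE-seq, in which DNA of low nucleosome occupancy is recovered from the aqueous phase after crosslinking and phenol extraction and then sequenced, in wandering Drosophila larvae of the third instar, labelled -6 h relative to puparium formation (APF). Per the labels, 8 libraries from female animals fall into 4 groups of 2, each made from at least 40 dissected tissues: wild type (WT) wing imaginal discs, WT leg imaginal discs, WT salivary glands, and wing discs that express an RNAi hairpin against the ecdysone receptor gene EcR (EcR-RNAi) through a vg-GAL4 driver with a flip-out tubulin GAL4 cassette. The names of the gland peaks carry the prefix EcRmimic and a size tag, where those of WT wing and leg carry OR and no such tag, although the labels call all of these groups wild type; what the prefix stands for is not known here, so the gland may come from another stock. Nothing in the labels says whether the libraries of a group came from separate crosses or days, so the adjusted p of the comparison tables measures only the spread between these libraries, which may be technical.

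Per the submitters' processing notes, the reads were handled with Bowtie2 2.3.4.1, SAMtools 1.9, Picard 2.2.4, bedtools 2.26, MACS2 2.1.2 and R 3.5.2, on genome build dm6, and DESeq2 is named without a version; the authors' labels of the comparison tables also carry its name. The names of all 4 peak lists carry tags for trimming and duplicate removal, and that of gland alone a size range. Otherwise the order and settings of these steps are not given in the sources used here. Values of 2 kinds were used. The authors deposited 1 peak list per group, made on merged libraries, with a fold enrichment (a ratio to the caller's local background), a pileup-derived score, and −log10 p-value and −log10 q-value per peak, and the values of a list were used only to describe, rank or filter its own peaks. The authors deposited also 4 comparison tables over 1 shared set of 13008 regions, each with a mean normalized count over all 8 libraries (a signal scaled by the authors), a log2 fold change with its standard error (SE), a test statistic, a p-value and an adjusted p-value. In all 4 tables the mean normalized count of a region was the same value, as it is when 1 model is fitted to all libraries. The sign of each log2 fold change followed the table's own category column, so a positive value is higher in the first group. Regions with a missing adjusted p (681 in wing against leg and 465 in wing against EcR-RNAi wing, all with a mean normalized count of at most 32.1 and 28.9) were never counted as called.

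A region was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. No count per library was used, because the tables hold none, so the comparisons were not refitted and the depth of each library is unknown. The precision is that of the SEs: their median was 0.22 in each of the 4 authors' deposited tables, and in wing against leg it was 0.33 for regions under the lower quartile of the mean normalized count (70.8) and 0.16 for those above the upper quartile (197.7). Folds of low-count regions are therefore less certain. The fold over its SE is not always the deposited statistic from which the p-values follow, so the folds and SEs look moderated. Among called regions they differed by more than 5% at 145 in wing against gland, 336 in leg against gland, 10 in wing against EcR-RNAi wing and none in wing against leg, by up to 2.07 times. Where the fold over its SE exceeded the statistic, a large fold beside its SE overstates the evidence, so the adjusted p is the measure of it. Centred folds had their p recomputed from fold and SE; without centring this gave 251 and 274 regions for wing and leg, 2751 and 1647 for wing and gland, 2934 and 1726 for leg and gland, and 170 and 100 for WT and EcR-RNAi wing. The authors' table lists a log2 fold change of exactly 0 with a p-value of 1 for 6 regions in wing against leg, as is given where no library of either group has a read; the reads themselves were not seen, and no fold is given for these regions.

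Gene names came from a RefSeq gene table of the same assembly as dm6 with gene starts and ends but no strand, exons or sequence. Each region was assigned to the protein-coding or listed gene whose nearest end, at either side, lay closest to the region centre (13946 genes used). The plan had named the transcription start; without strand both gene ends stood in for it, and a region within 500 bp of any gene end was counted as near a gene end. Exonic, intronic and untranslated positions were not assigned, and motif content was not analysed here because no genome sequence was used. Of the 303 symbols in the 14 gene lists fixed before the data were examined, all but 1 matched the gene table, but many of these genes were nearest to no region (13 of 31 gland list genes and 2 of 11 fat body genes had one). The lists cover ecdysone response, wing identity and patterning, leg identity and patterning, salivary gland function, myoblasts, tracheal cells, haemocytes, fat body, neurons and neural precursors, the E(spl) complex and Notch targets, cell cycle, cuticle and chitin, larval muscle structure, and housekeeping genes as a negative control.

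For each list, comparison and direction, the share of the list's regions that were called was set against 10000 random gene lists matched on the number of regions per gene, as a two-sided permutation p with Benjamini-Hochberg adjustment over the 112 tests; 0.0002 is the smallest p these draws can give. After the results had been seen, all list tests were repeated with 10 other sets of random draws, because some adjusted p lay close to 0.05. Calls within a list were also counted with p-values adjusted over the list alone. Peak lists were compared by overlap of at least 1 bp, with chance from 100 circular shifts along each arm. The share of called regions near gene ends, and the calls of the EcR-RNAi comparison among regions that differ between leg and salivary gland, were tested with two-sided Fisher's exact tests. The leg against salivary gland table was used for the latter because it shares no library with wing against EcR-RNAi wing. For comparisons that share the WT wing, the correlation and covariance with no effect were simulated from the SEs. Named genes followed a rule fixed before the data were examined: per comparison and direction, the 8 called regions with the largest absolute log2 fold change among those with at least the median mean normalized count, 1 per gene; up to 3 genes per list with the largest called change; and, in the EcR-RNAi comparison, every called ecdysone list gene and all regions of EcR. The text prints part of these.

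The procedures were first tested on simulated data. With the SEs of wing against leg and 200 of 13008 regions changed by a log2 fold of 2, 99.0% of the changes were recovered with 2 calls among unchanged regions, and of 80 tests of unchanged gene lists 5.00% had a p under 0.05. The simulated folds were drawn from these SEs and tested with the same SEs. Their recovery therefore checks the calculation only, not the deposited adjusted p behind the main calls. For the list tests calls were placed at random on single regions, so neighbouring genes that change together were not simulated. The alternatives tried were stricter and looser thresholds, adjustment without the authors' count filter, folds centred on the median of all regions or of regions near gene ends, filters on count and chromosome, other rules of overlap and gene assignment, and distances to gene ends. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.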

Results

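FAIRE-seq signal was collected from 8 libraries in 4 groups of 2: wing discs, leg discs and salivary glands of wild type larvae, and wing discs expressing EcR-RNAi, all at -6 h APF. The merged peak lists held 29283 peaks in WT wing, 26754 in WT leg, 16840 in WT salivary gland and 18464 in EcR-RNAi wing, with median widths of 236, 230, 152 and 274 bp. Fold enrichments in these lists are the authors' own, with medians of 2.82, 2.97, 3.82 and 3.39. WT wing peaks overlapped 81.8% of leg peaks, against 12.6% on average with circularly shifted peaks, and 79.1% of EcR-RNAi wing peaks, against 13.3%. They overlapped 44.7% of salivary gland peaks, against 10.4%, and leg peaks overlapped 45.4% of them, against 9.43%. The other way round, 74.1% of WT wing peaks were overlapped by leg peaks, 50.6% by EcR-RNAi wing peaks and 23.2% by salivary gland peaks. Under reciprocal overlap of at least 50% of both peaks, the gland shares fell to 16.19% and 17.35%, and those of leg and EcR-RNAi wing peaks with wing to 69.01% and 68.14%. The gland list alone carries a size tag and has the narrowest peaks. How far its widths and overlaps follow from how that list was made was not tested. Each observed overlap exceeded all 100 shifts (permutation p = 0.01, the smallest they can give). Each list was called on merged libraries, so the numbers of peaks have no replicate check. The 4 comparison tables covered 13008 shared regions with a median width of 509.5 bp and a median mean normalized count of 120.2. Of these regions, 4684 lay within 500 bp of a gene end. Depth per library is unknown.

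Wing and leg discs were compared to find open chromatin that differs between serially related appendages. The wing list had a larger share of regions higher in wing, and the leg list of regions higher in leg, than random lists. The authors' deposited table called 251 regions higher in WT wing and 272 in WT leg, 4.24% of the 12327 regions with an adjusted p. Of 265 regions of the wing identity list, 30 at 15 genes were higher in wing and 8 at 5 genes higher in leg in the authors' deposited table. The first share (11.3%) exceeded that of matched random lists (3.22%, permutation p = 0.0002, adjusted p = 0.00448). Of 251 regions of the leg identity list, 51 at 15 genes were higher in leg and 8 at 5 genes higher in wing in the authors' deposited table. The share higher in leg (20.3%) exceeded that of random lists (3.82%, permutation p = 0.0002, adjusted p = 0.00448). Adjusted over the list alone, the authors' deposited table gave the same counts of 30, 8, 51 and 8.

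Among wing genes, the largest change in the authors' deposited table lay at kn, a regulator of wing vein formation. That region, at 2R 14782549 to 14784041 inside a gene, was higher in wing by a log2 fold of 1.99 (SE 0.19, adjusted p = 3.9e-23, authors' deposited table). Regions at salr (1.72, SE 0.29), which patterns the central wing, and wg (1.55, SE 0.22), the Wnt ligand, followed in the authors' deposited table. The wing selector vg had 6 of 8 regions higher in wing, and bs, which specifies intervein cells, 6 of 9 in the authors' deposited table. There were 3 each at mirr and salr, 2 at Dr, and 1 each at kn, wg, nub, pdm2, ara, caup, Bx, bi, tup and vn in the authors' deposited table. Wing list regions higher in leg lay at rho (1.82, SE 0.20), dve (1.78, SE 0.22), en (1.58, SE 0.27), ara and wg in the authors' deposited table.

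The Hox gene Ubx, which specifies identity of the third thoracic segment, had 13 of 20 regions higher in leg in the authors' deposited table. The largest change there, at 3R 16676698 to 16677383, was a log2 fold of 2.77 (SE 0.22, adjusted p = 2.05e-31, authors' deposited table). Ubx thus held 13 of the 51 leg list regions higher in leg. The sample titles name leg but no thoracic segment, so segment is not separated from appendage type at Ubx. Regions of bab2 (2.01, SE 0.18), a distal leg regulator, and Sp1 (1.94, SE 0.19), a leg growth gene, were also higher in leg in the authors' deposited table. Sp1 and Lim1 had 6 such regions each, H15 and disco-r 5 each, and btd 3 in the authors' deposited table. The opposite direction was seen in the authors' deposited table at hth (1.69, SE 0.28), Dll (1.60, SE 0.16), which acts in distal parts of both appendages, drm (1.35, SE 0.21), tsh and 3 regions of dysf. Outside the lists, among regions of at least the median count, those near fd96Cb (2.41, SE 0.18), CG9360 (2.38, SE 0.19), Atf-2 (2.27, SE 0.19) and TfAP-2 (2.21, SE 0.21) were highest in leg in the authors' deposited table. Those highest in wing, at such counts, lay near CG14820 (4.36-fold), ppk and NAT1 (3.73-fold each), CG5321, Ttc30, Gp150 and Osi21 in the authors' deposited table.

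Lists of other cell types had few calls between the discs. No region of the myoblast, haemocyte, neural, E(spl) and Notch target, cell cycle, cuticle, muscle or housekeeping lists was called in the authors' deposited table (DESeq2, by the authors' own labels of the tables). At an unadjusted p under 0.05 there were 5 in each direction for myoblasts, 4 and 1 for cell cycle, 2 and 1 for cuticle, 1 and 0 for muscle, 0 and 0 for haemocytes, and 0 and 1 for the other lists. The tracheal gene trh had 2 regions higher in wing and 1 in leg in the authors' deposited table. Adh of the fat body list had 1 higher in leg (1.37, SE 0.18), and toe of the gland list 1 higher in wing (1.42, SE 0.30) in the authors' deposited table. The ecdysone list had 3 called of 226 in the authors' deposited table, at br (1.07, SE 0.25, higher in wing) and at Eip93F in each direction. Near gene ends lay 4.78% of the regions higher in wing and 5.88% of those higher in leg, against 37.8% of regions not called (Fisher's exact p = 2.54e-34 and 5.6e-34). A further 3 calls higher in leg, 2 over w (white) and 1 at His2Av, had SEs of 0.32, 0.44 and 0.47 in the authors' deposited table. Their SEs in leg against gland were at least 1.97 times the median of regions of like count.

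Salivary glands are polytene secretory tissue, and their comparison with the discs asks which open chromatin separates distant tissues. Against random lists, the Notch target list passed for both discs and the leg list for leg, while the cuticle list for wing and the gland list against leg passed, but not in all sets of draws. The authors' deposited tables called 2751 regions higher in WT wing and 1647 in gland, and 2934 higher in WT leg and 1725 in gland. Both discs were higher than gland at 2133 regions, and gland was higher than both at 1424 in the authors' deposited tables. The gland peaks carry another name prefix than the disc peaks, so stock may differ along with tissue. No library here measures DNA copy number. At any region higher in a disc, fewer copies in the polytene gland are therefore not separated from less open chromatin.

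The list of the E(spl) complex and other Notch targets had 12 of 18 regions higher than gland in each disc in the authors' deposited tables. E(spl) genes held most of these, with Ocho, Tom and, for wing, Brd in the authors' deposited tables. These shares (66.7%) exceeded those of random lists for wing (13.2%) and leg (14.7%; permutation p = 0.0002 and adjusted p = 0.00448 for both), and 0 regions were lower, also at an unadjusted p under 0.05. Genes of the E(spl) complex are neighbours, and the random lists were not matched for that. These p-values therefore count linked genes as separate and overstate the evidence if neighbours change together. The largest change lay near E(spl)mbeta-HLH at 3R 26002157 to 26003711, with 2.43 (SE 0.17) for wing and 2.65 (SE 0.17) for leg in the authors' deposited tables. Near E(spl)malpha-BFM and E(spl)m2-BFM the authors' deposited table gave 2.35 (SE 0.15) and 2.08 (SE 0.16) for leg. The leg identity list had 162 of 251 regions higher in leg than gland in the authors' deposited table (64.5% against 37.6%, permutation p = 0.0002, adjusted p = 0.00448). Ubx (3.01, SE 0.16), Antp (2.89, SE 0.19) and Poxn (2.80, SE 0.21) came first in the authors' deposited table. The wing list had 132 of 265 regions higher in wing than gland in the authors' deposited table, which did not pass (49.8% against 34.4%, permutation p = 0.014, adjusted p = 0.112). Its first genes were Ser (2.41, SE 0.17), en (2.33, SE 0.17) and Doc3 (2.31, SE 0.19) in the authors' deposited table.

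Cuticle and gland lists stood at the edge of the threshold. Of 26 cuticle and chitin regions, 11 were higher than gland in each disc in the authors' deposited tables (adjusted p = 0.0448 for wing and 0.0672 for leg, permutation), among them Cda4 (2.57, SE 0.18), dy (1.72, SE 0.18) and Cht2 (1.58, SE 0.15) in leg. For wing the adjusted p was under 0.05 in only 1 of 10 other sets of permutation draws (0.0476 to 0.0733), and it was 0.0686 with Fisher's exact test and 0.0751 (permutation) with only regions within 10 kb of a gene end. Of 53 gland list regions, 19 at 10 genes were higher in gland than leg in the authors' deposited table (35.8% against 12.2%, permutation p = 0.003, adjusted p = 0.048). That adjusted p was under 0.05 in 5 of 10 other sets of permutation draws (0.0299 to 0.0672) and 0.139 without a fold threshold. Against wing, 16 regions were higher in gland in the authors' deposited table (adjusted p = 0.0948, permutation). Regions at the glue gene Sgs4 (2.76, SE 0.39 over leg), Pgant4 (2.39, SE 0.34), which glycosylates mucins, and CrebA (2.69, SE 0.39 over wing), a regulator of secretory capacity, were among them in the authors' deposited tables. The gland selector fkh had 3 of its 4 regions higher in gland than leg, while tna had 3 of 4 higher in leg (2.28, SE 0.19) in the authors' deposited table. Outside the lists, among regions of at least the median count, those near CG1636 (3.69, SE 0.18), gus (2.84, SE 0.35), Cyp28d2 (2.71, SE 0.33), TpnC41C (2.56, SE 0.21) and SteXh:CG42398 (2.32, SE 0.25) were highest in gland over leg in the authors' deposited table. A region near CG43149, at 3L 39986 to 40985, was also called, but its wing against leg value is listed at 0 and no fold is given. These regions near CG1636, gus, Cyp28d2, SteXh:CG42398 and CG43149 were called higher in EcR-RNAi wing than WT wing too. For them a stock difference was not excluded (below). The mean normalized count is taken over all 8 libraries, so its floor favours regions with signal in more groups than gland.

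Ecdysone response genes were called in both directions between discs and gland. Of 226 regions, 57 were higher in leg and 25 in gland in the authors' deposited table, neither share apart from random lists (adjusted p = 0.426 and 1, permutation). All 8 regions of Blimp-1 (largest 2.58, SE 0.16), 6 of 8 of EcR, 5 of 7 of ImpE1 and 4 of 4 of rpr were higher in leg in the authors' deposited table. Of 20 Eip75B regions, 5 were higher in gland and none in leg in the authors' deposited table. At br the authors' deposited table had 5 regions higher in leg (largest 2.48, SE 0.16) and 3 in gland (largest 2.63, SE 0.35), and at Eip74EF 6 and 5.

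Among lists of other cell types, the tracheal list had 46 of 77 regions higher in wing than gland in the authors' deposited table, with vvl (2.80, SE 0.17) and knrl (2.68, SE 0.18) first. None was lower, and 2 were at an unadjusted p under 0.05; the list did not pass (adjusted p = 0.372, permutation). The myoblast list had 21 of 37 higher in wing in the authors' deposited table (adjusted p = 0.0622, permutation), led by sca (2.50, SE 0.17). Regions higher in wing made up 6 of 15 for haemocytes (gcm 2.13, SE 0.19), 11 of 50 for cell cycle (stg 1.89, SE 0.14), 4 of 26 for neurons (futsch 1.58, SE 0.25) and 2 of 4 for fat body (Lsp1gamma 1.23, SE 0.18) in the authors' deposited table. None of these shares differed from random lists (adjusted p = 0.23 to 1, permutation). Higher in gland than wing in the authors' deposited table were 5 neural regions, all of nvy (largest 2.06, SE 0.22), 1 of 2 muscle regions, at TpnC73F (2.07, SE 0.30), and 3 cell cycle regions, with E2f1 (1.59, SE 0.26) first. So were 3 myoblast regions, at mbc (1.78, SE 0.30), htl (1.13, SE 0.23) and Mef2 (1.04, SE 0.19), and the haemocyte gene Pvr (1.88, SE 0.37) in the authors' deposited table.

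**Figure D1:**
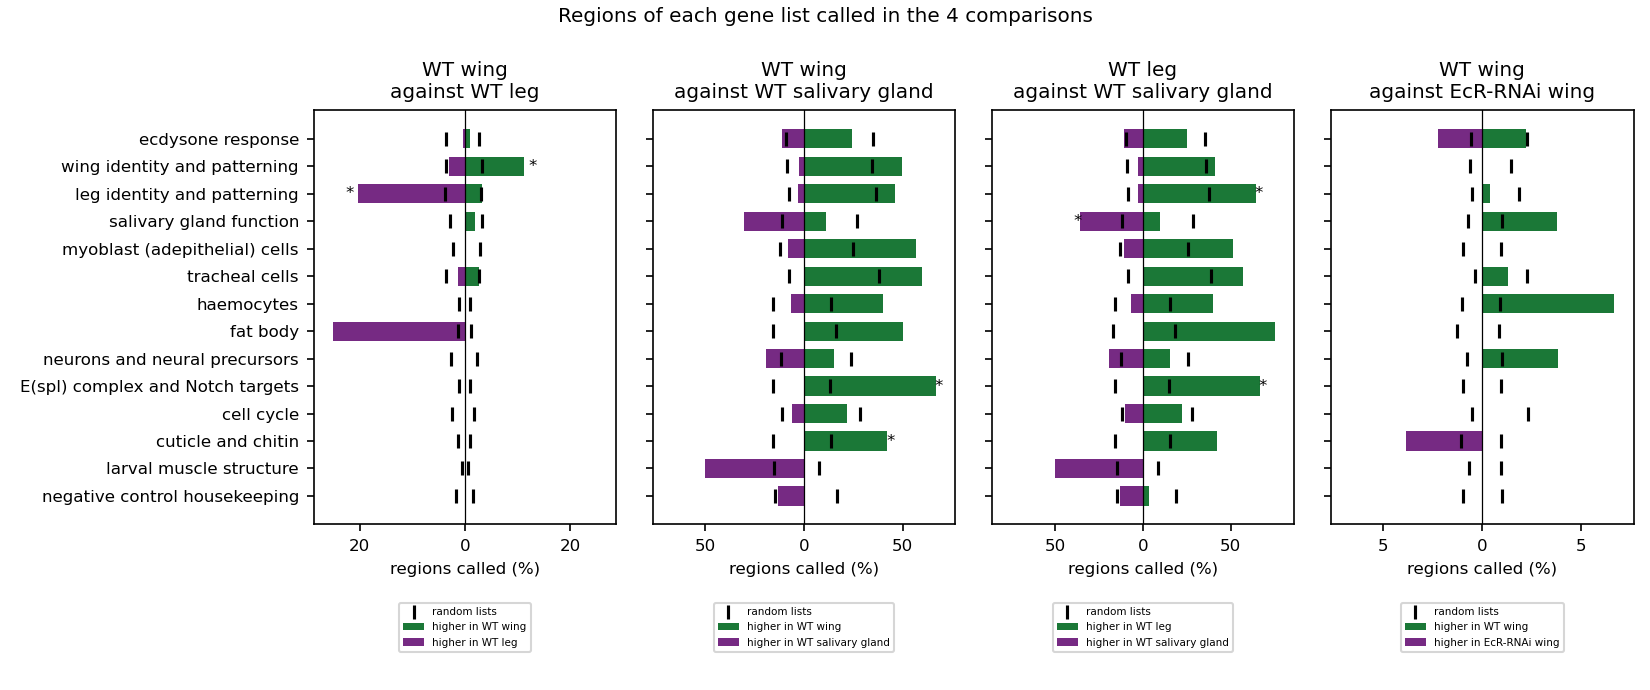
Share of the regions of each gene list that were called (percent, x axis) in each of the 4 comparisons, to the right for regions higher in the first group and to the left for the second; black ticks are the mean of 10000 matched random lists and asterisks an adjusted p under 0.05. Leg identity regions reached 20.3% higher in leg against wing and regions of the E(spl) and Notch target list 66.7% higher in either disc against gland.

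Housekeeping regions had a median log2 fold of -0.43 in wing against gland and -0.42 in leg against gland in the authors' deposited tables. Of 31, 4 were higher in gland in each comparison and 1, at Act5C, higher in leg in the authors' deposited tables. All regions near gene ends had medians of -0.36 and -0.37, against 0.50 for other regions in both. The split of calls depended on this scale: as deposited 62.6% of calls between wing and gland were higher in wing. This became 48.8% with folds centred on the median of all regions (0.18) and 82.7% with folds centred on regions near gene ends. Leg against gland gave 62.97%, 51.1% and 81.8%. Regions higher in gland had a median mean normalized count of 44.4, against 182 for those higher in wing, and 1235 of the 1647 lay under the lower quartile. Near gene ends lay 16.3% of the regions higher in wing than gland and 34.2% of those higher in gland, against 42.6% of those not called (largest Fisher's exact p = 1.86e-10). For leg these were 17.5% and 32.1%, against 43.3%. Without a fold threshold the gland shares turned to 53.63% and 51.8%, above the regions not called.

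Some regions far from any gene toward the centromeres, and on the Y, had large changes over gland. A region at X 23387526 to 23387963, 279413 bp from the nearest gene end, was 53.9-fold higher in wing than in gland in the authors' deposited table. A Y region at 988676 to 989929 was 35.3-fold higher in the authors' deposited table. The 44 regions between 23 and 24 Mb of X had a median log2 fold of 4.42 in leg over gland in the authors' deposited table, but the 8 between 4 and 5 Mb of 2R had -1.44. All 14 Y regions were called higher in wing and in leg than gland in the authors' deposited tables, although all libraries are labelled female. A region inside a gene near CadN, at 2L 17749673 to 17750310, was higher in wing by 4.42 (SE 0.25) in the authors' deposited table. Without the Y, the 1 Mb bins with a median log2 fold of leg over gland of at least 2 and a few other doubted regions, an alternative chosen after seeing the data, 2670 regions were higher in wing and 1639 in gland.

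**Figure D2:**
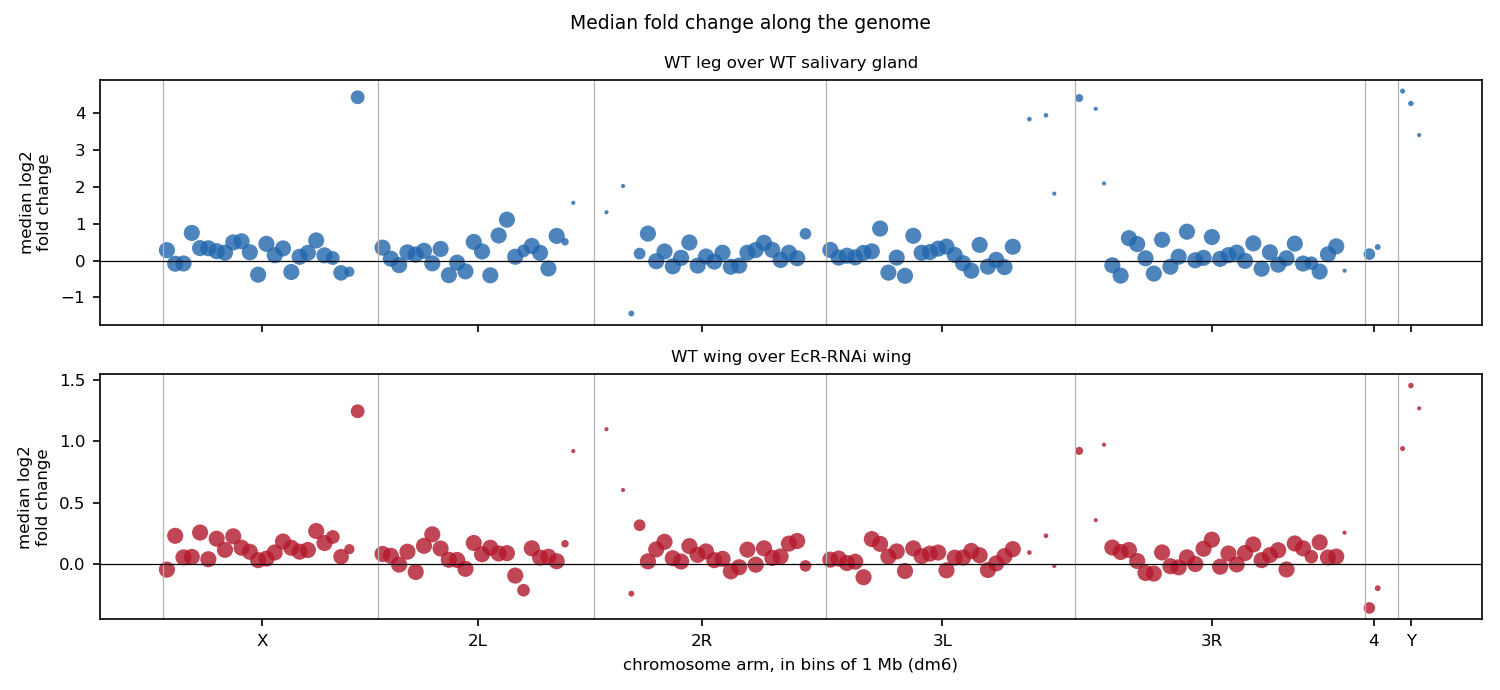
Median log2 fold change of the regions in each 1 Mb bin along the chromosome arms (dm6), for WT leg over WT salivary gland (top) and WT wing over EcR-RNAi wing (bottom); larger points hold more regions. The last bin of X stands at 4.42 in the top panel and 1.25 in the bottom panel.

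Wing discs with EcR-RNAi were compared with WT wing to ask which open chromatin depends on the ecdysone receptor. EcR itself had 1 of 8 regions higher in WT and 2 higher in EcR-RNAi wing in the authors' deposited table. The largest of these changes lay inside the gene at 2R 6093263 to 6094021, where EcR-RNAi wing exceeded WT by 4.72-fold (log2 2.24, SE 0.23, adjusted p = 1.86e-19, authors' deposited table). The same region did not pass the test in WT wing against leg or gland (adjusted p = 0.939 and 0.523, authors' deposited tables). A region beyond the other end, at 2R 6169461 to 6169719, was 2.47-fold higher in EcR-RNAi wing (adjusted p = 0.0015, authors' deposited table). An internal region at 2R 6108497 to 6109115 was higher in WT by 1.01 (SE 0.23, adjusted p = 0.000857, authors' deposited table). FAIRE does not measure EcR transcript or protein, so these values do not check the knockdown. What share of the disc cells expressed the hairpin is not known here. A region that was not called is therefore not shown to be independent of EcR. The reads were not seen, so signal from the hairpin construct itself cannot be told apart from signal of the EcR gene.

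**Figure D3:**
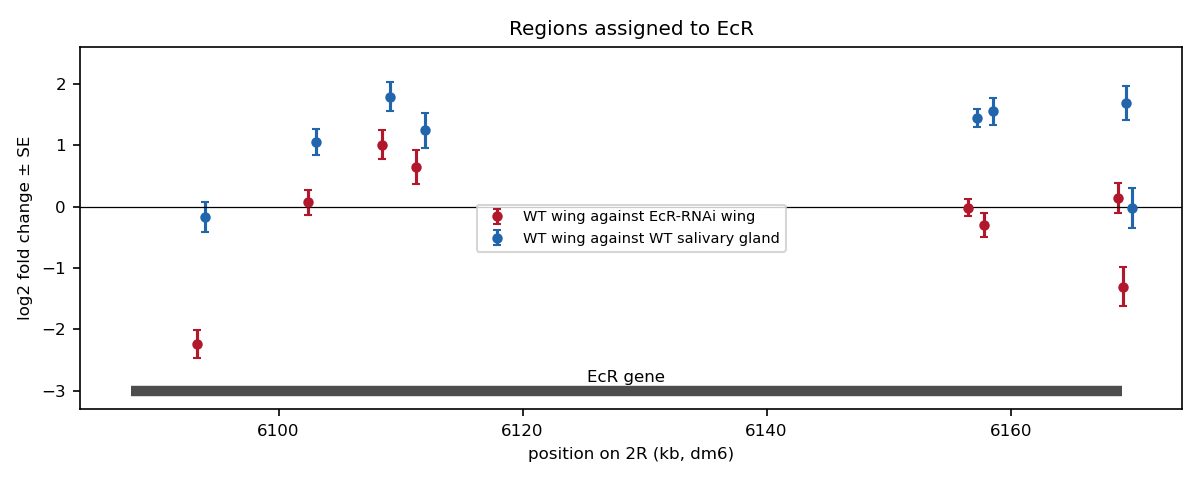
Log2 fold change with its SE (bars) for the 8 regions assigned to EcR, against position on 2R (kb, dm6; points of the 2 comparisons are set 0.7 kb apart for legibility), with the annotated gene as a grey bar. The leftmost region stands at -2.24 in WT wing against EcR-RNAi wing and at -0.17 in WT wing against salivary gland.

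Other ecdysone response genes were called in both directions. Higher in WT wing in the authors' deposited table were regions at vri (1.12, SE 0.20), Eip74EF (1.12, SE 0.31), Blimp-1 (1.09, SE 0.24) and br (1.02, SE 0.20). Higher in EcR-RNAi wing in the authors' deposited table were regions at E23 (1.25, SE 0.21), an ecdysone-induced transporter, Eip93F (1.11, SE 0.21) and ftz-f1 (1.08, SE 0.17), a nuclear receptor of the mid-prepupal stage. With EcR, 5 of 226 regions of the list were called in each direction in the authors' deposited table, and 5 in each adjusted over the list alone. Neither share differed from matched random lists (adjusted p = 0.936 for WT and 0.186 for EcR-RNAi wing, permutation). Centring the folds on their median over all regions (0.08) left br (0.94), EcR (0.93), vvl (0.94) and Pgant4 (0.92) below the fold threshold.

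Over all regions the authors' deposited table called 156 higher in WT wing and 99 in EcR-RNAi wing, 2.03% of the 12543 with an adjusted p. Centred on the median of all regions the counts were 120 and 139, so the share higher in WT went from 61.2% to 46.3%. Among regions of at least the median count, the highest in WT in the authors' deposited table lay near ATbp (2.29, SE 0.23, in the X stretch above), tweek (2.16, SE 0.23), PPO2 (1.81, SE 0.25), a prophenoloxidase of crystal cells, and Br140 (1.78, SE 0.27). Regions near Tab2 (1.32, SE 0.24), SK (1.29, SE 0.21), Nrg (1.23, SE 0.25) and Ggt-1 (1.20, SE 0.22) followed in the authors' deposited table. Those highest in EcR-RNAi wing in the authors' deposited table lay near CG1636 (4.45, SE 0.17), SteXh:CG42398 (4.29, SE 0.23), CG9380 (2.39, SE 0.55), EcR (2.24, SE 0.23, above), gus (2.09, SE 0.34), mam (1.61, SE 0.19), the Notch coactivator, and w (1.49, SE 0.44). The region near CG43149 whose wing against leg value is listed at 0 was called too. That region and those near CG1636, SteXh:CG42398, CG9380, gus and mam were also called higher in gland than in both discs. For this set a difference of fly stock was not excluded (below). Near gene ends lay 17.3% of the regions higher in WT and 25.3% of those higher in EcR-RNAi wing, against 36.7% of those not called (Fisher's exact p = 2.2e-07 and 0.0208). Without a fold threshold the 2 shares were nearly equal, at 29.49% and 29.33%.

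No share of calls in the tissue identity lists passed the test against random lists. None of the 265 wing list regions was called in the authors' deposited table, where 112 were higher in WT and 13 lower at an unadjusted p under 0.05 with DESeq2. Random lists had 1.48% higher in WT (adjusted p = 0.482, permutation). Of the 251 leg list regions 1 was called higher in WT in the authors' deposited table (0.398% against 1.85%, adjusted p = 0.586, permutation), with 89 higher and 12 lower at an unadjusted p under 0.05. The median log2 fold was 0.32 for both lists in the authors' deposited table, against 0.08 over all regions. Higher in WT in the authors' deposited table were single regions of Antp of the leg list (1.10, SE 0.23), vvl of the tracheal list (1.02, SE 0.20), PPO2 of the haemocyte list and nvy of the neural list (1.10, SE 0.36). The gland list had 2, at Sgs3 (1.25, SE 0.26) and Pgant4 (1.00, SE 0.26), in the authors' deposited table. The cuticle gene dyl had a region higher in EcR-RNAi wing (1.02, SE 0.23) in the authors' deposited table. No region of the myoblast, fat body, E(spl) and Notch target, cell cycle, muscle or housekeeping lists was called with DESeq2 in the authors' deposited table. At an unadjusted p under 0.05 these had 9, 1, 6, 9, 0 and 4 regions higher in WT and 4, 0, 2, 7, 0 and 5 lower. The groups differ in genotype beyond the hairpin, since drivers are labelled only in the EcR-RNAi animals, and no driver-only group is among these samples.

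Changes with EcR-RNAi followed the contrast between disc and gland in WT, although the gland may come from another stock. Among 2918 regions higher in WT leg than gland, 2.78% were higher in WT wing than EcR-RNAi wing, against 0.779% elsewhere (odds ratio 3.64, Fisher's exact p = 6.47e-15). In the same class 0.171% were higher in EcR-RNAi wing, against 0.977% (odds ratio 0.174, exact p = 1.75e-06). Among 1368 regions higher in gland than leg, 3.14% were higher in EcR-RNAi wing, against 0.501% elsewhere (odds ratio 6.44, exact p = 1.09e-16). In that class 0.365% were higher in WT wing, against 1.35% (odds ratio 0.268, exact p = 0.000676). Of the 43 regions behind the odds ratio of 6.44, 40 were also higher in gland than wing. Of these 40, 42.5% lay within 50 kb of another, and a stock difference was not excluded for them (below). The exact tests count such neighbours as separate regions. Near gene ends alone, neither odds ratio under 1 passed the threshold (exact p = 0.353 and 0.514), and without the Y, the bins of high leg over gland fold and other doubted regions the 3.64 became 2.05 and the 0.174 became 0.114. Without a fold threshold in either table all 4 kept their direction but not their size: the 6.44 fell to 1.922, while 3.64, 0.174 and 0.268 became 5.455, 0.3563 and 0.1196. Across regions, which are not independent replicates, the log2 folds of WT wing over EcR-RNAi wing and of leg over gland correlated with r = 0.419 (covariance 0.215), and these comparisons share no library. With wing over gland, which shares the WT wing, r was 0.444 and the covariance 0.218, against 0.508 and 0.0297 simulated with no effect. With wing over leg r was 0.00972 and the covariance 0.00181, below the 0.484 and 0.0296 simulated. The simulated values may thus not describe these folds, and they are only a rough yardstick for wing over gland too. Of the 156 regions higher in WT wing than EcR-RNAi wing, 77 were also higher in wing than gland, against 34.04 for independent lists. Of the 99 higher in EcR-RNAi wing, 47 were higher in gland than wing, against 10.4, and the shared WT wing libraries add to both numbers.

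**Figure D4:**
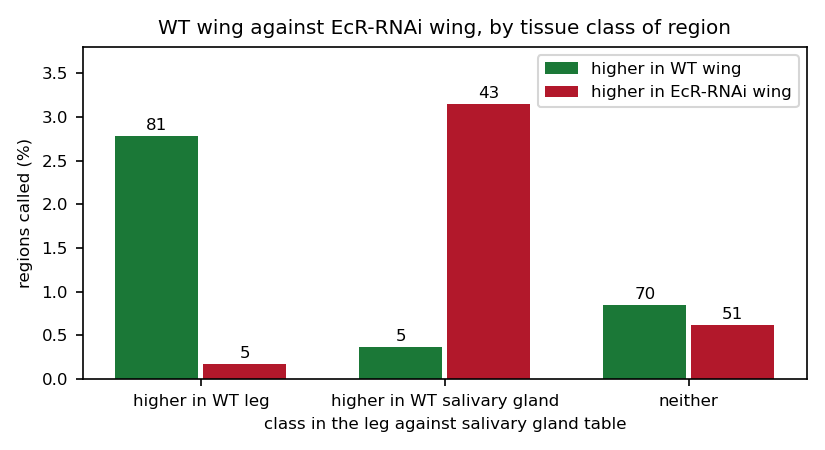
Share of regions (percent, y axis) called higher in WT wing or in EcR-RNAi wing, for regions higher in WT leg, higher in WT salivary gland or neither in the leg against salivary gland comparison; numbers above the bars are regions. Regions higher in gland reached 3.14% higher in EcR-RNAi wing (43 regions) against 0.365% higher in WT wing (5 regions).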

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

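No paired analysis was possible because the tables hold no value per library; for the same reason leave-one-out, a replicate block and other size factors were not run, and motif settings were not run without a genome sequence. The gene assignment alternative took 2 kb on both sides of a gene, since strand was not used. Without a fold threshold, 622 regions were higher in wing and 647 in leg, 5273 in wing and 3660 in gland, 5263 in leg and 3635 in gland, and 1302 in WT and 675 in EcR-RNAi wing. At an absolute log2 fold of at least 2 these were 2 and 19, 443 and 256, 620 and 280, and 10 and 14. Folds centred on regions near gene ends gave 4367 and 915 for wing and gland and 4529 and 1007 for leg and gland, as the shift moves every region alike. At or above the lower quartile of count, 412 and 422 regions were higher in gland than in wing and leg, and 91 were higher in WT and 63 in EcR-RNAi wing, with fewer regions counted. The count is a mean over all 8 libraries, of which 2 are gland, so this filter removes gland calls more than disc calls by construction. Without regions higher in gland than in both discs, a choice made after seeing the data, 59 were higher in EcR-RNAi wing. Every other count of called regions stayed within 1.5 times under the alternatives run. Shares of overlapping peaks exceeded all shifts under each of the 4 other rules, the lowest being gland peaks with wing and leg at reciprocal 50% overlap (16.19% and 17.35%). Low counts limit the precision: the median SE under the lower quartile was 0.31 to 0.33 in the authors' deposited tables.

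Lists that passed numbered 2 with more calls in wing against gland and 3 in leg against gland, and 0 with fewer. By gene body these were 7 and 7 with more and 3 and 4 with fewer; within 10 kb, 2 and 3 with fewer. Without a fold threshold, 4 had more in wing against gland, 4 and 6 had fewer, and 1 had fewer in wing against leg. Fisher's exact test gave 6 and 6 with more and 4 and 4 with fewer. The cause was not tested, and counts from random lists also move with the draws: over 10 other sets, chosen after seeing the data, the cuticle list passed in 1 and the gland list in 5, and the wing list, with fewer calls in gland over wing, in 2. Without a fold threshold 53.63% and 51.8% of the regions higher in gland than wing and leg lay near gene ends, which reversed the direction; the cause was not tested. Near gene ends alone, the odds ratios of 0.3291 (higher in EcR-RNAi wing among regions higher in leg) and 0.3433 (higher in WT among regions higher in gland) kept their direction but did not pass, with fewer regions tested. The EcR region at 2R 6102400, never called, went from 0.07 to -0.0123 when centred on the median.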

Other observations

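The regions in this paragraph were chosen after their values were seen. Regions at vg and alphaTub84B, loci named in the driver genotype, were picked for an adjusted p under 0.05 between WT wing and EcR-RNAi wing. Their changes lay below the fold threshold, and the other vg regions did not pass that adjusted p. Of all 12543 regions with an adjusted p, 1302 were higher in WT and 675 in EcR-RNAi wing without a fold threshold. Such a difference is therefore not particular to these loci. In the authors' deposited table a region inside vg, at 2R 12888320 to 12889878, was higher in EcR-RNAi wing (0.58, SE 0.17, adjusted p = 0.0114). The same region was higher in WT wing than in leg (1.35, SE 0.19, authors' deposited table). The region at the vg gene end, at 2R 12884093 to 12884758, was higher in WT (0.50, SE 0.15, adjusted p = 0.0146, authors' deposited table). At alphaTub84B, a region at 3R 7085413 to 7087538 was higher in EcR-RNAi wing (0.65, SE 0.14, adjusted p = 0.000493, authors' deposited table). Of the 1424 regions higher in gland than in both discs, 40 were also higher in EcR-RNAi wing than WT wing in the authors' deposited tables. The largest changes with EcR-RNAi among these lay near CG43149, mthl8, mdu, CG1636 and SteXh:CG42398. The 40 also held 3 regions near Cyp28d2, 2 near gus and 1 each near CG9380, mam, bnl, cv-c and shot.

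Of the tests below, those of the SE at w and His2Av and of the share of centromere-proximal regions higher in WT wing than EcR-RNAi wing were chosen after the result was seen.

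A set of 6 regions, 4 of them between 29656 and 51316 on 3L, was listed at 0 between WT wing and leg while gland and EcR-RNAi wing were called higher in the authors' deposited tables. A candidate explanation is sequence that differs between fly stocks: of the 40 regions above, 42.5% lay within 50 kb of another, against a median of 5% and a 95th percentile of 17.5% in 1000 draws from the 1424 regions. The name prefix of the gland peaks differs from that of the discs, which leaves the stock of the gland open. If loss of EcR opened gland regions, the 19 gland list regions higher in gland than leg would shift toward EcR-RNAi wing, but their median of WT over EcR-RNAi wing was -0.0934 (95% bootstrap interval -0.36 to 0.03), too wide to decide. Neighbouring regions would also lie in clusters if a locus opened as a whole, so over the 40 regions loss of EcR and stock cannot be told apart. The 6 regions listed at 0 had mean normalized counts of 36.1 to 124.5. No other of the 13008 regions was listed at 0 between the discs, although counts went down to 11.6. These counts are means over all 8 libraries and do not give the disc signal of a region. The values of 0 therefore do not decide between loss of EcR and stock at these 6 either. The reads themselves were not seen.

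Signal over w was higher in WT leg than WT wing at X 2788994 to 2793294 (1.77, SE 0.32) and 2795957 to 2796789 (1.95, SE 0.44), and at His2Av by 1.58 (SE 0.47), in the authors' deposited table. Over w, EcR-RNAi wing was also higher than WT wing (1.28, SE 0.32, and 1.49, SE 0.44, authors' deposited table). The planned test of extra copies of w, of the kind used as a transgene marker, decides nothing: leg peaks covered 0% of the 2662 bp between these regions, but so did every other peak list. In leg against gland all 3 SEs exceeded those of the 200 regions of nearest count (lowest percentile 100), so libraries of some group differed there. Since the SE pools all groups, opening of these genes in leg, extra copies of w and a library that differs from its label cannot be told apart.

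The Y and 7 bins of 1 Mb near centromeres held 87 regions; the bins were picked for a median log2 fold of leg over gland of at least 2, and others near centromeres, such as 4 to 5 Mb of 2R (-1.44), did not reach it. The planned test of lower copy number in gland, whose polytene chromosomes under-replicate heterochromatin, needed both kinds of region, but only 2 lay near gene ends (50% higher in leg). Copy number and closed chromatin in gland cannot be told apart. Of the 87, 93.1% were also higher in WT wing than EcR-RNAi wing in the authors' deposited table (median 1.04), against 89.8% (median 0.37) of the 541 regions elsewhere with a log2 fold of leg over gland of at least 2, which are not matched to the 87 in fold. Both shares lie near their ceiling, and no group has the driver stock without the RNAi, so stocks that differ in these repeats and loss of EcR cannot be told apart.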
